A study of Homo sapiens with 13 samples.

How the data were processed

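RNA-seq was analysed for 9 libraries of the human liver cancer line Huh7 (3 shControl, 3 shFKBP9 and 3 labelled shIGF2BP1), and m6A peak lists for 2 pull-down and input pairs of HepG2. Groups and replicate numbers were taken from the sample titles. Total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra II RNA kit, per the labels' protocols. Trim Galore, HISAT2, featureCounts and the build hg38 are named in the submitters' processing notes, without versions, roles or order. The strand setting, the annotation and the peak caller are not given in the sources used here. Reads of a gene and an overlapping or antisense partner could therefore not be told apart.

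The authors deposited 1 table per targeting hairpin with raw read counts per gene for 6 libraries, 13894 and 13857 genes with 13722 in common, already limited to genes with a mean count of about 5 or more. The shControl counts of genes found in both tables were the same. The same tables hold FPKM values that the authors computed from those counts, and count over FPKM gave the gene lengths used here. The authors' deposited tables of differential expression hold a log2 fold change with its standard error, a p-value and an adjusted p-value per gene. The authors' deposited table classes 1112 genes as up and 536 as down in shFKBP9, and 1291 and 1189 in shIGF2BP1. Its classes follow unadjusted p-values and a fold of at least 1.5, with adjusted p-values up to 0.106 and 0.167 among the classed genes. In the authors' deposited table IGF2BP1 had a log2 fold change of -0.43 (p = 0.0328, adjusted p = 0.124) in shIGF2BP1. The deposited peak lists give coordinates, a gene and a region per peak, and their only score is 0 for every peak. The combined list (9250 peaks of 150 bp), which has 24h in its name without a stated meaning, was annotated with HOMER, per the file headers; whether it came from pooled reads or from merged peaks is not stated there. Of its peaks 4701 (50.8%) overlapped both replicate lists and 1585 (17.1%) neither. An item is not reported here.

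Library totals were 36023653 to 43951533 counts. Each hairpin group was compared with shControl within its own table, as no label says that a replicate number marks a shared day. Genes were filtered with filterByExpr, scaled by trimmed means (TMM) and tested with robust glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The hairpin groups were compared directly in a fit over all 9 libraries. The same steps were tested on simulated data with 200 seeded genes drawn from the real means, library sizes and spread. Changes were seeded only in genes above a floor of mean count, so recovery of genes with few counts was not simulated. For shFKBP9, edgeR recovered 76.1%, 95.5% and 100% of genes changed 1.5-, 2- and 4-fold among 13255 genes, with 6 false calls of 187. For the libraries labelled shIGF2BP1 it recovered 7.46%, 41.8% and 93.9% among 13214 genes, with 4 false calls of 99, while DESeq2 1.42.0 made 60 false calls of 195 among 13857 genes. Small changes in the libraries labelled shIGF2BP1 were thus mostly out of reach.

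Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with adjustment over the lists that had at least 5 tested members. The 28 lists were m6A writers, erasers and readers, literature targets of IGF2BP1, the FKBP family, chaperones and the unfolded protein response, ATF4 and amino acid stress, G1/S genes, G2/M genes, p53 targets, MYC targets, liver-secreted proteins and enzymes, hepatocyte transcription factors, mesenchymal and matrix genes, epithelial junctions, interferon response, NF-kB response, glycolysis and hypoxia, cholesterol synthesis, fatty acid synthesis, WNT targets, YAP targets, apoptosis regulators, ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, immediate early genes, and markers of fibroblasts, endothelial cells and immune cells. The lists, the tests and most alternatives were fixed before the data were examined. Genes were named by a rule fixed then too: FKBP9 and IGF2BP1; up to 6 genes per direction with the largest change among called genes with a mean count of at least 100 in the higher group and no overlap between the groups; up to 4 members of each list with the smallest adjusted p; and up to 6 genes lower and 4 higher in both hairpin groups by the larger adjusted p, again among genes with peaks. From these, mostly genes whose call no alternative changed were described.

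Whether replicate numbers pair the libraries was checked by correlating deviations from the group means. For shControl and the libraries labelled shIGF2BP1 the same-number correlations were 0.56, 0.21 and 0.36, all above 0.1, although replicate 3 correlated better with another number (0.54) and replicate 2 nearly as well (0.20). By the rule of 0.1 the numbers were taken to pair these libraries and a blocked fit was run beside the unblocked one. Overlap of calls was set against independent lists, and the correlation of log2 changes against 20 simulations of unchanged groups sharing the controls. Peaks were compared with GenomicRanges 1.54.1 at a minimum overlap of 1 bp, and gene positions come from a RefSeq table of the same build. A gene counted as an m6A gene when both replicate lists named it; odds ratios come from two-sided Fisher's exact tests. Figures were drawn with matplotlib 3.10.9.

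Alternatives were DESeq2, RLE size factors, library totals, no low-count filter or at least 1 CPM in 3 libraries, the replicate block, all 9 libraries in 1 fit, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 0.5, a 2-fold threshold, an estimated inter-gene correlation, fry, other definitions of m6A genes, expression strata and leaving out each library in turn. Voom with quality weights, scaling alternatives for the lists, strata of expression and length, list differences matched by deciles of length and expression, separate controls for each hairpin group, an estimated correlation within each other list alternative, and peaks inside the gene's bounds were added after seeing the data. The motif search in peaks was not run, as no genome sequence was used here, and no stricter peak threshold was possible with scores of 0.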

Results

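The transcriptome of Huh7, a line derived from a human hepatocellular carcinoma, was sequenced after lentiviral delivery of short hairpin RNAs. The 9 libraries fell into 3 groups of 3, a control hairpin (shControl), a hairpin named for FKBP9 (shFKBP9) and a hairpin named for IGF2BP1 (shIGF2BP1). The labels name no further hairpin for either target and no rescue. Effects of a hairpin on other transcripts therefore cannot be told apart from effects of losing its target. FKBP9 encodes a peptidyl-prolyl isomerase of the endoplasmic reticulum, and IGF2BP1 encodes an RNA-binding protein known as a reader of N6-methyladenosine (m6A) in mRNA. Sites of m6A were mapped in a second liver cancer line, unmodified HepG2, by antibody pull-down of methylated RNA fragments against input, with 2 replicates. A combined peak list of these cells carries 24h in its name, which no label explains. The RNA-seq libraries held 36023653 to 43951533 counted reads each. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread among these libraries, part of which may be technical. All 9 RNA-seq libraries carried the same batch label, and the HepG2 libraries carried another.

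The abundance of each targeted mRNA was examined first, in every library. FKBP9 mRNA fell about 15-fold in the shFKBP9 libraries, from 141 ± 0.700 to 9.51 ± 0.350 CPM (read counts scaled to library size after normalisation, mean ± SD, n = 3 each), with a log2 fold change of -3.89 (SE 0.0850, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.69e-24). IGF2BP1 mRNA did not pass the test in these libraries (log2 fold change 0.06, adjusted p = 0.527 by the edgeR test). In the libraries labelled shIGF2BP1, IGF2BP1 mRNA stood at 345, 224 and 278 CPM in replicates 1, 2 and 3 when all 9 libraries were scaled together, against 341, 411 and 392 CPM in shControl. The level in replicate 1 thus lay within the control range. The log2 fold change of IGF2BP1 was -0.41 (SE 0.179), and the edgeR quasi-likelihood test did not call it (adjusted p = 0.157, and 0.173 with the replicate number as a block). Without replicate 1 of these libraries the adjusted p was 4.32e-06, and it was 0.0480 in a fit over all 9 libraries. The mRNA level therefore does not by itself check the label of replicate 1, and directions below are those of the libraries labelled shIGF2BP1. FKBP9 mRNA in these libraries stood at 250, 171 and 213 CPM against 136, 138 and 138 CPM in shControl (log2 fold change 0.64, SE 0.161, edgeR adjusted p = 0.0290). That call was lost without shControl replicate 1, 2 or 3 (adjusted p = 0.0629, 0.111 and 0.0677) and without replicate 3 of the libraries labelled shIGF2BP1 (0.103).

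**Figure D1:**
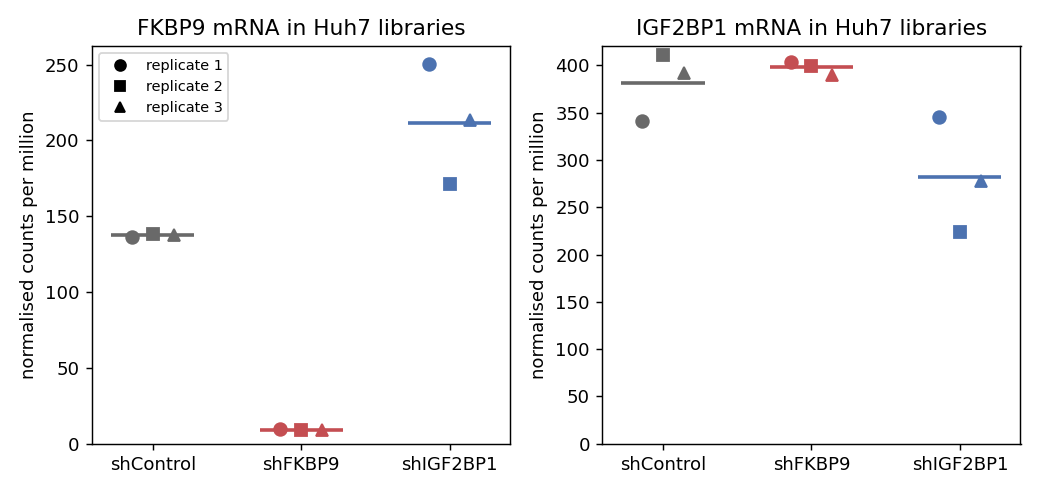
FKBP9 mRNA (left) and IGF2BP1 mRNA (right) in CPM, scaled over all 9 Huh7 libraries, with 1 point per library and a line at each group mean. The shFKBP9 libraries lie at 8.98 to 9.66 for FKBP9, and replicate 1 of the libraries labelled shIGF2BP1 lies at 345 for IGF2BP1, within the shControl range.

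The comparison of shFKBP9 with shControl asked which transcripts differ in the libraries where FKBP9 mRNA had fallen. More genes rose than fell among liver-secreted proteins and enzymes (20 against 4 of 33) and in fatty acid synthesis (10 against 0 of 13). More fell than rose among ribosomal proteins (69 against 0 of 73), MYC targets (19 against 1 of 29) and NF-kB response genes (8 against 0 of 17). None of these list shifts was called when the correlation among genes was estimated (camera adjusted p = 0.300 to 0.435). Among single genes, CNN1, which encodes the actin-binding protein calponin 1, rose from 1.55 ± 0.466 to 8.89 ± 0.544 CPM (mean ± SD, n = 3 each), and SLC38A3, a glutamine transporter gene, rose from 5.04 ± 0.562 to 20.4 ± 0.705 CPM. RFK, encoding riboflavin kinase, fell from 39.5 ± 2.22 to 10.3 ± 0.601 CPM. The edgeR quasi-likelihood test called 5833 of 13320 genes at the adjusted threshold of 0.05, of which 2938 were higher and 2895 lower, and with library totals in place of trimmed-mean scaling 3331 higher and 2303 lower. The median absolute log2 change of the called genes was 0.41, and 473 called genes changed by at least 2-fold (319 higher, 154 lower). When all 9 libraries shared 1 estimate of the spread, only 1650 genes were called (677 higher, 973 lower).

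Among called genes with a mean count of at least 100 in the higher group and no overlap between the groups, the largest rises in shFKBP9 beyond these were those of ROBO2 (log2 fold change 2.19), an axon guidance receptor gene, CDC20B (1.97) and CPN2 (1.96), which encodes a subunit of plasma carboxypeptidase N. ANKRD36C also rose (2.10), but it has close paralogs that share reads, so its value is uncertain, and its adjusted p was 0.0583 in the fit over all 9 libraries and 0.0785 with library quality weights. In the same set the largest falls after FKBP9 itself were those of VSIG1 (-2.43), B4GALNT4 (-2.01), N4BP3 (-1.96), RFK (-1.94) and GAL (-1.93), the galanin precursor gene. Apart from ANKRD36C, each of these genes passed the edgeR test with an adjusted p of at most 2.83e-06.

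Of the 28 gene lists fixed before the data were examined, 12 were shifted in shFKBP9 by limma's camera test with its preset inter-gene correlation of 0.01, 4 upward and 8 downward. None of the 12 calls held when the correlation was estimated from these libraries, and each such p is given beside its list. Calls were lost even where the estimated correlation lay below 0.01, for immediate early genes (-0.013), WNT targets (-0.024) and fibroblast markers (-0.025). Their loss is thus not due to a higher correlation among genes. Fatty acid synthesis lost its call too, at an estimated correlation of 0.018, close to the preset. With an estimated correlation camera takes its p-values from the residual degrees of freedom of the fit, which are few with so few libraries. With the preset it uses the number of genes instead. The estimated setting therefore has little power here, which was not simulated. A lost call does not show that a list was unchanged. In the list of liver-secreted proteins and enzymes, 20 of 33 tested genes rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 6.76e-05, adjusted p = 0.351 with an estimated correlation). The fibrinogen chain gene FGG rose from 332 ± 12.5 to 777 ± 57.0 CPM (n = 3 each), FGB by a log2 fold change of 0.99 and the apolipoprotein gene APOA1 from 222 ± 14.2 to 482 ± 25.5 CPM. TTR, which encodes transthyretin, went the other way, from 316 ± 29.5 to 173 ± 5.57 CPM. In the fatty acid synthesis list 10 of 13 genes rose and none fell (11 adjusted over the list alone, camera adjusted p = 4.97e-05, adjusted p = 0.300 with an estimated correlation). They included GPAM, the acyltransferase gene of glycerolipid synthesis (log2 fold change 1.66), PNPLA3 (1.02), ACSS2 (0.68) and SCD, the stearoyl-CoA desaturase gene (0.47).

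Of the 73 cytosolic ribosomal protein genes, 69 fell and none rose (70 adjusted over the list alone), with a mean log2 change of -0.41 (camera adjusted p = 1.66e-14, adjusted p = 0.435 with an estimated correlation). Against genes of the same length and expression their median log2 difference was -0.18, in place of a raw -0.41. RPS19 fell from 639 ± 59.3 to 411 ± 31.5 CPM and RPL11 from 693 ± 48.0 to 482 ± 16.7 CPM (n = 3 each). Ribosomal protein genes have many processed pseudogenes, so single values are uncertain. Short genes tended to fall and long genes to rise in this comparison: the Spearman correlation across genes between log2 change and gene length was 0.357. The median log2 change was -0.24 in the shortest 10% of genes and 0.28 in the longest. In the MYC target list 19 of 29 genes fell and 1 rose (21 lower adjusted over the list alone, camera adjusted p = 6.76e-05, adjusted p = 0.300 with an estimated correlation). Examples were FBL, the fibrillarin gene (-0.68), MRTO4 (-0.49), ODC1 (-0.48) and RRP9 (-0.47).

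In the NF-kB response list 8 of 17 genes fell and none rose (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0141, adjusted p = 0.300 with an estimated correlation), among them RELB (-1.10), NFKB2 (-0.82) and the chemokine genes CCL20 (-0.82) and CXCL8 (-0.68). Of the immediate early genes 7 of 13 fell, also adjusted over the list alone (camera adjusted p = 0.0227, adjusted p = 0.300 with an estimated correlation), with FOS at -0.88, FOSL1 at -0.71 and IER2 at -0.53. In the ATF4 and amino acid stress list 10 of 22 genes fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00927, adjusted p = 0.330 with an estimated correlation), including SLC3A2, a subunit gene of amino acid transporters (-0.67), and PPP1R15A (-0.44). In the glycolysis and hypoxia list 14 of 27 genes fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.00927, adjusted p = 0.330 with an estimated correlation). Examples were PKM, the pyruvate kinase gene, from 2777 ± 253 to 1796 ± 57.0 CPM, and PFKFB3 at -0.60. In the G1/S list 22 of 46 genes fell and 5 rose (22 and 6 adjusted over the list alone, camera adjusted p = 0.0222, adjusted p = 0.330 with an estimated correlation). GMNN, the geminin gene, changed by -1.14 and the replication licensing gene MCM3 by -0.71, and without shControl replicate 2 the list's adjusted p was 0.0577. Matching for length and expression, chosen after seeing the data, also moved the median log2 difference of other called lists. It went from -0.25 to -0.15 for MYC targets, -0.48 to -0.30 for NF-kB and -0.28 to -0.16 for glycolysis. For G1/S it went from -0.14 to -0.04 and for mitochondrially encoded genes from 0.13 to 0.49. Smaller moves were those of liver-secreted proteins (0.43 to 0.52), fatty acid synthesis (0.38 to 0.33) and ATF4 (-0.24 to -0.17). WNT targets (-0.25 to -0.26), immediate early genes (-0.18 to -0.21) and fibroblast markers (0.28 to 0.24) also moved little.

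The last 3 called lists in shFKBP9 rested on fewer genes and on single libraries. In the WNT target list 5 of 14 genes fell and none rose (camera adjusted p = 0.0478, adjusted p = 0.300 with an estimated correlation), among them CCND1, the cyclin D1 gene, from 358 ± 20.9 to 225 ± 11.9 CPM (n = 3 each), and NOTUM at -2.21. Of 13 mitochondrially encoded genes 5 rose (camera adjusted p = 0.0320, adjusted p = 0.469 with an estimated correlation). Of 6 fibroblast and stellate cell markers 3 rose, LUM, the lumican gene, by 0.95 (camera adjusted p = 0.0478, adjusted p = 0.300 with an estimated correlation). Each count was the same adjusted over the list alone. The WNT list's adjusted p was 0.0696, 0.0679 and 0.0769 without shControl replicate 2, shControl replicate 3 and shFKBP9 replicate 3. The mitochondrial list's was 0.179, 0.0895 and 0.0629 without shControl replicate 2, shFKBP9 replicate 2 and shFKBP9 replicate 3, and the marker list's was 0.0842, 0.0555 and 0.0656 without the same 3 libraries. With a low-count filter of 1 CPM in 3 libraries the WNT and marker lists had adjusted p = 0.103 and 0.0513.

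The remaining lists did not pass the camera test in shFKBP9. Many of their genes changed, but so did 43.8% of all tested genes. Hepatocyte transcription factors had 10 of 17 genes higher and 2 lower, NR1I2 (0.99) and ONECUT1 (1.12) among the higher ones (camera adjusted p = 0.0594, and 0.0412 without shControl replicate 1, where it was 0.314 with an estimated correlation). Literature targets of IGF2BP1 had 10 of 22 higher and 5 lower (0.230), with the growth factor gene IGF2 rising from 323 ± 22.3 to 790 ± 19.2 CPM (n = 3 each), PEG10 rising by 0.62 and E2F1 falling by 0.51. The writers, erasers and readers of m6A had 9 of 22 higher and 3 lower (0.641), with HNRNPC at -0.39. Other members of the FKBP family had 3 of 12 higher and 2 lower (0.655), FKBP4 at -0.64. Chaperones and the unfolded protein response had 5 of 28 higher and 7 lower (0.386), the kinase gene EIF2AK3 at 0.91 and SDF2L1 at -0.64. Epithelial junction genes had 2 of 15 higher and 8 lower (0.108), and mesenchymal and matrix genes 6 of 19 higher and 3 lower (0.415), with TAGLN at 1.15 and LOXL2 at -0.82. Cholesterol synthesis had 9 of 24 higher and 2 lower (0.308), interferon response 7 of 16 and 2 (0.350), and p53 targets 2 of 21 and 4 (0.809), with GDF15 at -0.78. G2/M genes had 19 of 54 higher and 16 lower (0.661), YAP targets 5 of 15 and 4 (0.861), apoptosis regulators 6 of 18 and 4 (0.731), and replication-dependent histones 1 of 16 and 2 (0.856). Of 5 immune cell markers CD68 (0.46) rose and 2 fell, including LYZ, the lysozyme gene (-1.53), with a list p of 0.343. None of the 3 endothelial markers tested passed the gene test. Adjusted over the list alone, no count among these lists moved by more than 1 gene. The numbers in brackets after the counts are camera adjusted p-values.

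**Figure D2:**
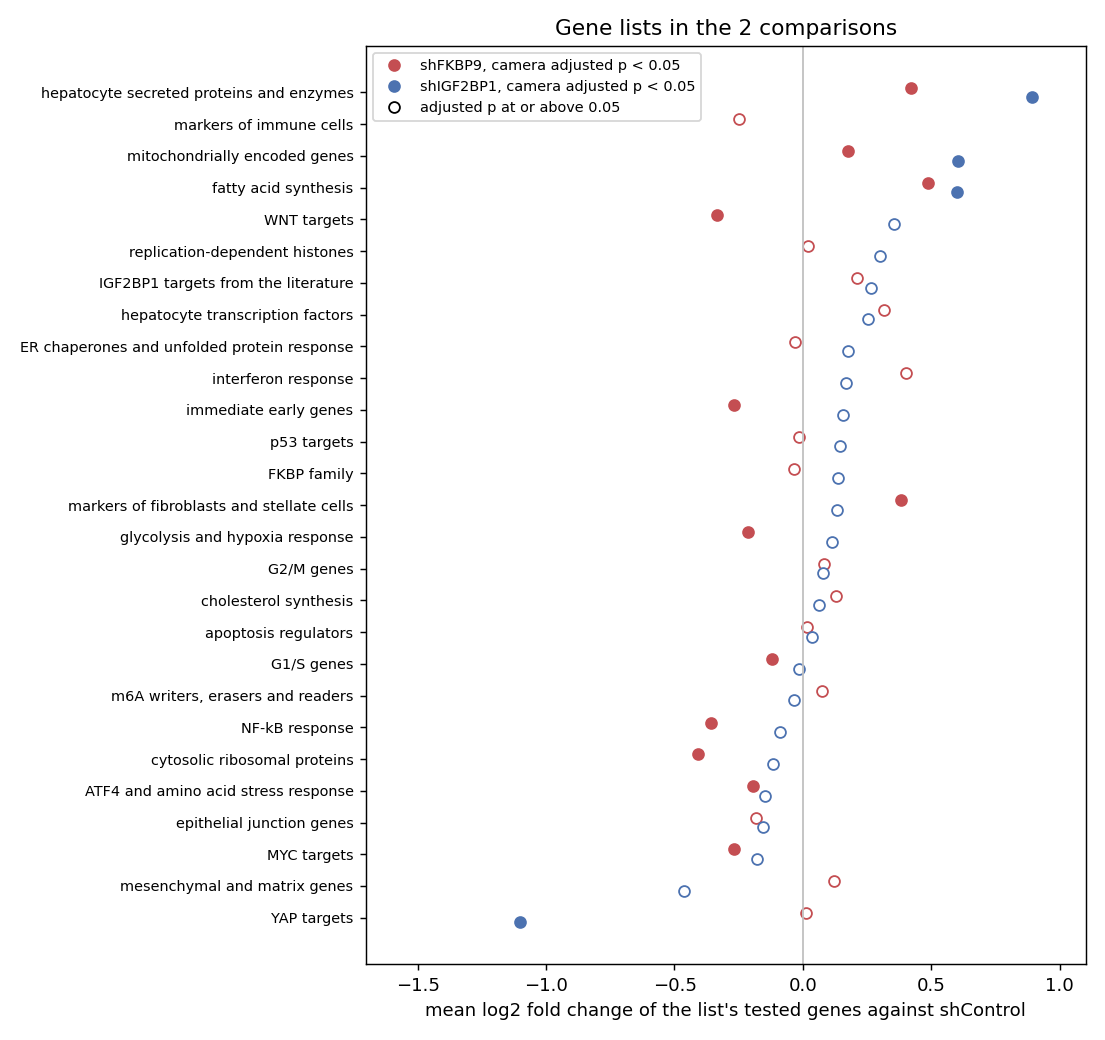
Mean log2 fold change against shControl of the tested genes of each gene list, for shFKBP9 (red) and the libraries labelled shIGF2BP1 (blue), with filled points where the camera test's adjusted p was below 0.05 (preset correlation 0.01). Ribosomal proteins stand at -0.41 in shFKBP9, and liver-secreted proteins at 0.89 and YAP targets at -1.10 in the libraries labelled shIGF2BP1. No filled point held with an estimated correlation, a setting with few degrees of freedom and little power.

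The comparison of the libraries labelled shIGF2BP1 with shControl asked which transcripts change when IGF2BP1 is targeted. Among liver-secreted proteins and enzymes 20 of 33 genes rose and none fell, and among YAP targets 11 of 15 fell and 1 rose. Neither list shift was called when the correlation among genes was estimated (camera adjusted p = 0.338 and 0.458). TF, the transferrin gene, rose from 679 ± 19.5 to 2702 ± 317 CPM (mean ± SD, n = 3 each) and the complement gene C3 from 225 ± 9.41 to 978 ± 200 CPM. ANKRD1, a stretch-responsive gene, fell by a log2 fold change of -3.97, and NPPB, the natriuretic peptide B gene, from 57.9 ± 10.9 to 0.790 ± 0.276 CPM. The edgeR quasi-likelihood test called 2048 of 13207 genes at the adjusted threshold of 0.05, 1239 higher and 809 lower, and with library totals in place of trimmed-mean scaling it called 1206 higher and 1326 lower. The called genes had a median absolute log2 change of 0.89, and 814 of them changed by at least 2-fold (416 higher, 398 lower). The count depended on single libraries: it was 1353, 950 and 1092 without shControl replicates 1, 2 and 3, and 4279, 3164 and 918 without replicates 1, 2 and 3 of the libraries labelled shIGF2BP1. The fit over all 9 libraries called 3506 genes and limma voom with library quality weights, chosen after seeing the data, 7540, with a weight of 10.6 on replicate 3 of the libraries labelled shIGF2BP1 against 0.147 and 0.333 on replicates 1 and 2. The biological coefficient of variation was 27.8% among these 3 libraries, against 9.46% in shControl and 6.45% in shFKBP9. Of 2133 genes chosen because they separated replicates 1 and 2, replicate 3 lay between them for 99.8%.

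Among called genes with a mean count of at least 100 in the higher group and no overlap between the groups, SAA1, LCN2, SLPI, RCSD1, MBOAT4 and HP rose most in the libraries labelled shIGF2BP1. The acute phase gene SAA1 had 2 counts in the 3 control libraries together and 490 in the 3 libraries labelled shIGF2BP1, a ratio of 237 (95% counting interval 65.3 to 1964), and reads shared with its near-identical neighbour make the gene uncertain. LCN2, the lipocalin 2 gene, rose from 0.0307 ± 0.0532 to 6.40 ± 1.02 CPM (n = 3 each) and SLPI, a protease inhibitor gene, from 1.02 ± 0.183 to 10.7 ± 1.61 CPM. RCSD1 rose by a log2 fold change of 3.24, MBOAT4, the ghrelin acyltransferase gene, by 3.10, and the haptoglobin gene HP, which has a close paralog, by 2.96. KRT4, a keratin gene, had 150 to 182 counts in each control library and none in any of the libraries labelled shIGF2BP1, at least 170-fold lower against a floor of 3 counts over the group. The chemokine receptor gene CXCR4 fell by 5.93 on the log2 scale (-5.93), and ARHGAP23 fell as well (-4.39). XAGE2 (-5.71) and ANXA8L1 (-4.80) also fell, and both have near-identical paralogs that make their values uncertain. Each of these genes had an edgeR adjusted p of at most 0.00123, and intervals and floors cover counting error only.

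Of the 28 lists, 4 were shifted in the libraries labelled shIGF2BP1 by the camera test, 3 upward and 1 downward. None of these calls held with an estimated correlation. As in shFKBP9, that setting had few degrees of freedom, so the lost calls do not show that the lists were unchanged. Of the liver-secreted proteins and enzymes 20 of 33 rose and none fell (23 adjusted over the list alone), with a mean log2 change of 0.89 (camera adjusted p = 1.30e-10, adjusted p = 0.338 with an estimated correlation). Beside TF and C3, HP rose from 5.50 ± 0.459 to 42.9 ± 5.35 CPM (n = 3 each) and the apolipoprotein gene APOC3 from 8.10 ± 0.511 to 31.1 ± 2.85 CPM. Of 15 YAP targets 11 fell and 1 rose, also adjusted over the list alone, with a mean log2 change of -1.10 (camera adjusted p = 1.77e-05, adjusted p = 0.458 with an estimated correlation). Beside ANKRD1, the matricellular protein gene CCN1 fell from 371 ± 22.6 to 76.8 ± 15.4 CPM, MYOF by a log2 fold change of -2.68 and the receptor kinase gene AXL from 5.08 ± 0.744 to 0.523 ± 0.102 CPM. In the fatty acid synthesis list 6 of 13 genes rose and none fell (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00731, adjusted p = 0.458 with an estimated correlation), including the desaturase genes FADS1 (1.36), FADS2 (1.12) and SCD (0.99). Of the mitochondrially encoded genes 6 of 13 rose (9 adjusted over the list alone, camera adjusted p = 5.59e-04, adjusted p = 0.676 with an estimated correlation). MT-ND2 among them rose by 0.79, and its edgeR adjusted p of 0.0225 became 0.0728, 0.108 and 0.0525 without shControl replicates 1, 2 and 3 and 0.0668 without replicate 3 of the libraries labelled shIGF2BP1.

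**Figure D3:**
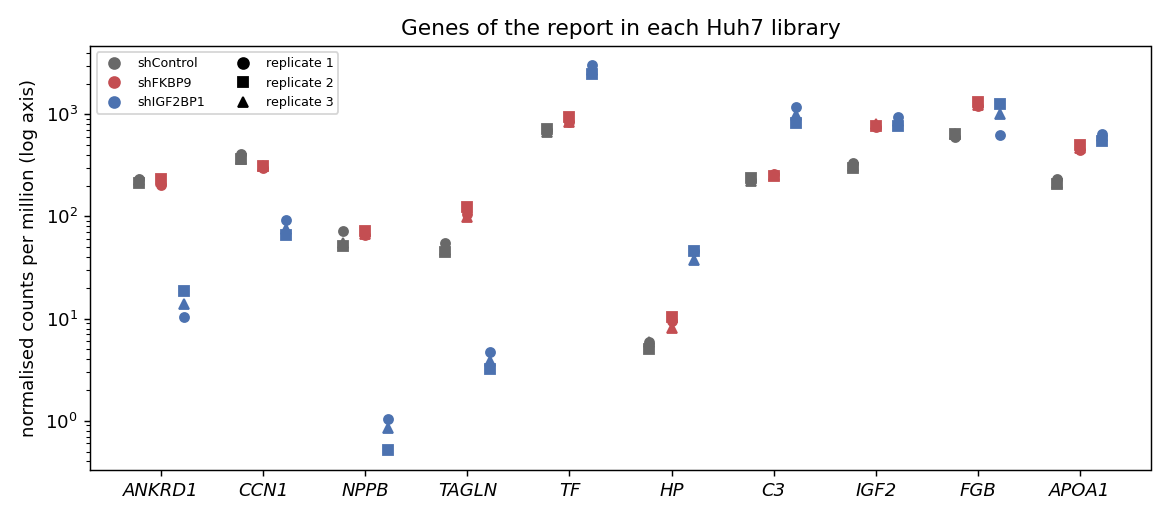
CPM (log axis, scaled over all 9 libraries) of 10 genes named in the report, with 1 point per Huh7 library, the group by colour and the replicate by symbol. ANKRD1, CCN1, NPPB and TAGLN lie below every shControl library in the libraries labelled shIGF2BP1, and IGF2 and APOA1 lie above every shControl library in both other groups.

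The remaining lists did not pass the camera test in the libraries labelled shIGF2BP1, and for many of them members moved both ways. The p-values in brackets are camera adjusted. The NF-kB response list had 4 of 17 genes higher and 4 lower (0.972): the chemokine genes CXCL8 and CXCL1 fell by 3.02 and 1.65 on the log2 scale, while TNFAIP3 rose by 1.05 and TNFAIP2 by 0.93, both encoding proteins induced by tumour necrosis factor. Immediate early genes had 5 of 13 higher and 2 lower (0.206), with SGK1 at 1.39 and FOSL1 at -2.06. ATF4 and amino acid stress had 3 of 22 higher and 4 lower (0.772), with the amino acid transporter gene SLC7A5 at -1.79 and DDIT4 at 0.97. Mesenchymal and matrix genes had 3 of 19 higher and 6 lower (0.111), TAGLN, the transgelin gene, falling from 48.1 ± 5.33 to 3.88 ± 0.823 CPM (n = 3 each) and LOX rising by 1.17. Epithelial junction genes had CDH1, the E-cadherin gene, higher (1.46) and 3 of 15 lower, KRT18 (-1.07), KRT19 (-0.93) and KRT8 (-0.82), with a list p of 0.488. KRT8 had an adjusted p of 0.0528 in the edgeR test without replicate 3 of the libraries labelled shIGF2BP1. Targets of p53 had 5 of 21 higher and 2 lower (0.591), BTG2 at 2.43 and PLK2 at -1.65. Apoptosis regulators had BCL2L11 (1.76) and BMF (1.38) higher and BOK (-1.87) lower among 19 tested (0.976). WNT targets had 4 of 14 higher and 2 lower (0.0696), with the glutamine synthetase gene GLUL at 1.31 and BMP4 at -1.27. Glycolysis and hypoxia had 7 of 27 higher and 4 lower (0.0645, and 0.0446 with the replicate block, where no list had an adjusted p below 0.689 with an estimated correlation), PFKFB4 at 1.58 and the glucose transporter gene SLC2A3 at -3.96. Replication-dependent histones had 3 of 17 higher (0.0645, and 0.0405 with the replicate block).

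Among the other lists in the libraries labelled shIGF2BP1, literature targets of IGF2BP1 had 5 of 22 genes higher and none lower (camera adjusted p = 0.111), with IGF2 rising from 307 ± 20.3 to 842 ± 97.8 CPM (n = 3 each). Hepatocyte transcription factors had 5 of 17 higher (0.0696), RXRA at 0.81 and PPARA at 1.05. Cholesterol synthesis had 3 of 24 higher, INSIG1 (1.13) and TM7SF2 (0.92) among them (0.674). Of 46 G1/S genes CCNE1, the cyclin E1 gene (1.44), and CDCA7 (0.72) rose (0.951), and none of 53 G2/M genes passed (0.532). None of 29 MYC targets passed (0.111), and ribosomal protein genes had 1 of 73 higher and 1 lower (0.0696). With a filter of 1 CPM in 3 libraries the ribosomal protein (0.0418), glycolysis and histone (0.0367 each) and WNT (0.0416) lists passed, and no list had an adjusted p below 0.252 with an estimated correlation in that fit. With library totals, chosen after seeing the data, ribosomal proteins (0.00287) and the glycolysis, hepatocyte transcription factor, histone and WNT lists (0.0354 each) passed, and with RLE size factors, also chosen afterwards, only ribosomal proteins did (0.0478). The m6A writers, erasers and readers had 1 of 22 higher (0.880), the FKBP family 2 of 12 (0.294), chaperones and the unfolded protein response 1 of 28 (0.0879), interferon response 1 of 15 (0.591), and fibroblast markers none of 6 (0.591). Of the immune cell markers LYZ (1.62) and CD68 rose among 4 tested, and of 3 endothelial markers ESAM fell (-2.35), too few for the list test. Adjusted over the list alone, the largest move among all lists not called was from 5 to 9 higher hepatocyte transcription factors, followed by 6 to 9 lower mesenchymal genes and 4 to 7 higher WNT targets. Without replicate 1 of the libraries labelled shIGF2BP1, 6 of these lists passed: ribosomal proteins (0.00232), G2/M genes (0.0496), and chaperones, hepatocyte transcription factors, MYC targets and histones (0.0456 each), with no adjusted p below 0.390 when the correlation was estimated. Without replicate 2 the WNT (0.0305) and glycolysis (0.0292) lists passed, as did the immune cell markers (0.0484), which had enough tested members there. Without shControl replicate 1 the glycolysis list passed (0.0367), and without shControl replicates 2 and 3 the ribosomal protein list passed (0.00840 and 0.0172). None of the lists that passed in any of these alternatives did so with an estimated correlation in the same fit (lowest camera adjusted p = 0.248). That setting has few residual degrees of freedom, and fewer still without a library or with the replicate block. It could therefore pass hardly any list, and its result does not decide whether these lists were shifted.

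The hairpin groups were then compared with each other in a fit over all 9 libraries. NPPB was 68.4 ± 2.71 CPM in shFKBP9 and 0.797 ± 0.265 CPM in the libraries labelled shIGF2BP1 (n = 3 each), and CXCR4 was 8.35 ± 1.21 and 0.185 ± 0.174 CPM. KRT4, absent from the counts of the libraries labelled shIGF2BP1, stood at 8.35 ± 0.410 CPM in shFKBP9, and XAGE2, uncertain for its paralogs, was higher there by 5.03 on the log2 scale. Lower in shFKBP9 were FKBP9 (-4.50), the amino acid transporter gene SLC6A14 (-3.77), the elastase inhibitor gene PI3 (-3.43) and LFNG, a Notch-modifying glycosyltransferase gene (-3.37). The edgeR quasi-likelihood test called 4031 of 13455 genes, 1694 higher and 2337 lower in shFKBP9. The count was 2503 without shFKBP9 replicate 1, 2503 without shFKBP9 replicate 3, and 6472 and 2562 without replicates 2 and 3 of the libraries labelled shIGF2BP1. By the camera test on the difference, the YAP targets were higher in shFKBP9 (mean log2 difference 1.14, adjusted p = 8.87e-06). The ribosomal protein (-0.27, 9.43e-07), glycolysis and hypoxia (-0.30, 1.24e-04), liver-secreted (-0.45, 6.39e-04), WNT (-0.67, 0.00410), immune marker (0.0173), chaperone (-0.19, 0.0181), mitochondrially encoded (-0.40, 0.0181) and immediate early (-0.40, 0.0205) lists were lower. With an estimated correlation the adjusted p was 0.355 for the YAP, glycolysis, liver-secreted, WNT, immune marker and chaperone lists, 0.659 for ribosomal proteins, 0.716 for mitochondrial genes and 0.631 for immediate early genes.

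Whether both hairpin groups moved the same transcripts was examined over the 13110 genes tested in both. Lower in both were the chemokine gene CXCL8, the heparan sulfate proteoglycan gene GPC1, the desmosomal plakin gene PPL, ARHGAP23, the retinoic acid receptor gene RARB and CER1. PPL, for example, fell from 72.5 ± 2.49 to 29.7 ± 3.91 CPM in shFKBP9 and from 69.0 ± 2.62 to 9.90 ± 1.94 CPM in the libraries labelled shIGF2BP1 (n = 3 each). Higher in both were the collagen gene COL2A1 (log2 fold changes 0.56 and 2.59), HP (0.73 and 2.96) and the neighbouring genes TMEM176A (1.02 and 2.25) and TMEM176B (0.91 and 2.46). In all, 810 genes were called in the same direction (477 higher, 333 lower) by the edgeR tests and 252 in opposite directions (96 higher and 156 lower in shFKBP9). Independent lists of these sizes would share 271 higher and 178 lower genes. Simulations of unchanged groups against the shared controls called at most 4 genes, so they give no expected number of shared calls. The correlation of log2 changes across genes was r = 0.223 (Spearman 0.216), below the mean of 0.339 (0.324 to 0.357) over 20 such simulations, genes not being independent replicates. The covariance was 0.0615 against a simulated 0.0169, a difference of 0.0446. With separate controls for each hairpin group, 1 and 2 libraries in 6 ways chosen after seeing the data, the correlation fell to a mean of 0.133 (0.0938 to 0.202) and the covariance to 0.0431 (0.0335 to 0.0628). Shared calls were not counted with separate controls, as 1 side would hold a single control, so part of the excess in shared calls may come from the shared control libraries. The same-direction count was 535, 423 and 442 without shControl replicates 1, 2 and 3, and 1928 and 394 without replicates 1 and 3 of the libraries labelled shIGF2BP1. The correlation was 0.109 without replicate 2 of those libraries.

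The m6A peak lists of HepG2 describe where methylated fragments were enriched over input. Replicate 1 held 9324 peaks and replicate 2 held 8338 peaks, each 151 bp wide as listed, in hg38 coordinates. Of these, 5196 overlapped a peak of the other replicate by at least 1 bp, 55.7% of replicate 1 and 62.3% of replicate 2. When 7716 peaks of replicate 1 were placed at random within their genes, 2.56% overlapped on average over 20 draws, against 56.7% as observed. The random positions covered introns as well, which held few of the listed peaks. The 2.56% is therefore likely too low as a chance level for mRNA fragments, and no draw within exons was made. Exons held 33.0% of replicate 1 peaks (95% exact binomial interval 32.1 to 34.0) and 34.8% of replicate 2 peaks (33.8 to 35.8), and 3' UTRs held 31.3% (30.4 to 32.2) and 29.1% (28.1 to 30.1). The 5' UTRs held 13.6% and 13.8%, transcription start sites 13.3% and 12.7%, introns 6.22% and 6.67%, and intergenic sequence 2.56% and 2.88%. Peaks in both replicates were found in 4107 genes.

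**Figure D4:**
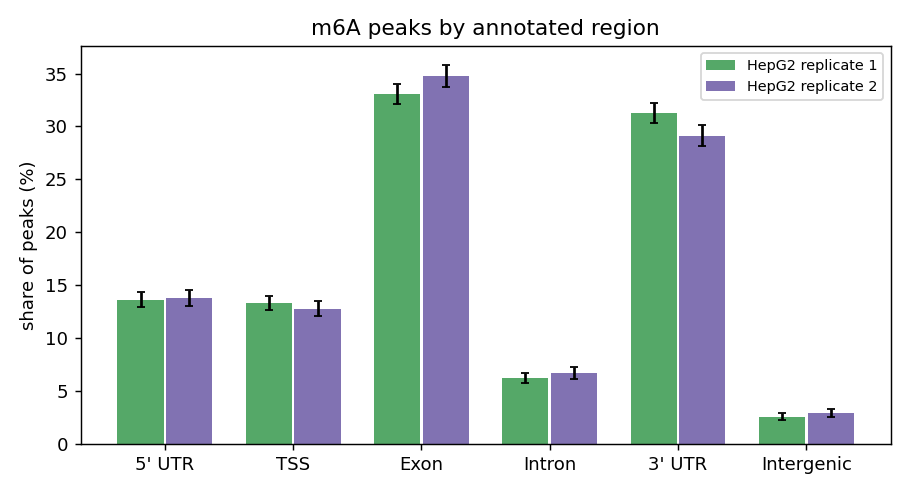
Share of m6A peaks (%) in each annotated region class for the 2 HepG2 replicates, with 95% exact binomial intervals as error bars. Exons hold 33.0% and 34.8% of the peaks and 3' UTRs 31.3% and 29.1%.

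Of the 23 literature targets of IGF2BP1, 9 had a peak in both HepG2 replicates. The proto-oncogene MYC (chromosome 8, 127735434 to 127742951) had 1 peak in its 3' UTR at 127740929 to 127741079 in both. The imprinted gene PEG10 (chromosome 7) had a 3' UTR peak at 94667076 to 94667226 in replicate 1 and 94667057 to 94667207 in replicate 2, and BTRC (chromosome 10) a 3' UTR peak at 101553313 to 101553463 and 101553232 to 101553382. FOXK1 (chromosome 7) shared a 3' UTR peak at 4767306 to 4767456 and 4767301 to 4767451. E2F1 (chromosome 20) had a 5' UTR peak at 33686166 to 33686316 and 33686178 to 33686328, and SRF (chromosome 6) at 43171495 to 43171645 and 43171496 to 43171646. ACTB and PDLIM7 had peaks at their transcription start sites, and the proliferation marker gene MKI67 had 7 peaks in replicate 1 and 6 in replicate 2. IGF2 (chromosome 11) had an exonic peak at 2147365 to 2147515 in replicate 1 only. FKBP9 (chromosome 7, 32957440 to 33006928) had 1 peak in its 3' UTR, at 33005299 to 33005449, in replicate 1 only, and no peak was listed for IGF2BP1 (chromosome 17, 48996558 to 49056145). The deposited lists give no height, fold or p for a peak, so peaks are not ranked.

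The HepG2 peaks were set against the calls in the Huh7 hairpin groups, with the limit that the sites were mapped in another cell line. In the libraries labelled shIGF2BP1, 488 of 3468 genes with a peak in both replicates rose (14.1%), against 743 of 9650 other genes (7.70%), an odds ratio of 1.96 (95% interval 1.73 to 2.22, two-sided Fisher's exact p = 2.63e-26). Fewer of them fell, 150 (4.33%) against 657 (6.81%), an odds ratio of 0.619 (0.512 to 0.743, Fisher's exact p = 7.82e-08). That last relation was not past the threshold without shControl replicate 3 (odds ratio 0.813, exact p = 0.0890). In shFKBP9, 923 of 3469 peak genes rose (26.6%) against 2003 of 9762 others (20.5%), an odds ratio of 1.40 (1.28 to 1.54, Fisher's exact p = 2.48e-13), and 692 fell (19.9%) against 2195 (22.5%), an odds ratio of 0.859 (0.779 to 0.946, Fisher's exact p = 0.00186). Genes with peaks were longer (median 4826 bases against 3579). Within strata of Huh7 expression and length, chosen after seeing the data, both shFKBP9 relations were lost. Their Mantel-Haenszel odds ratios were 1.01 for higher and 0.974 for lower genes. The relations of the libraries labelled shIGF2BP1 stayed past the threshold at 1.81 and 0.729. The strata did not use expression in HepG2, on which the listing of a peak depends, so they cannot remove its effect. The lower relation in shFKBP9 was also lost with the combined peak list (0.926, Fisher's exact p = 0.0943) and without shControl replicate 3 (0.917, exact p = 0.0873). Fisher's test takes genes as independent, which they are not. The camera test of all peak genes gave p = 0.309 in shFKBP9 (p = 0.523 with an estimated correlation) and p = 2.26e-04, upward, in the libraries labelled shIGF2BP1 (p = 0.344 with an estimated correlation).

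Of 333 genes lower in both hairpin groups, 59 had a peak in both HepG2 replicates (17.7%), against 26.6% of the 13023 genes compared, an odds ratio of 0.588 (95% interval 0.435 to 0.784, Fisher's exact p = 1.53e-04). They included PPL, the osteopontin gene SPP1, which fell by 0.53 and 2.70 on the log2 scale, the amphiregulin gene AREG (-0.68 and -2.36), the stress-response gene GADD45B (-0.61 and -1.66), the calcium channel gene CACNA1H (-1.06 and -2.90) and CCN1 (-0.30 and -2.27). In the fit over all 9 libraries SPP1 and CCN1 were not called in shFKBP9 (edgeR adjusted p = 0.114 and 0.129). Of 474 genes higher in both, 173 had such a peak (36.5%), an odds ratio of 1.62 (1.33 to 1.97, Fisher's exact p = 1.31e-06). Within strata of Huh7 expression and length, chosen after seeing the data, the Mantel-Haenszel odds ratio was 0.707 (0.531 to 0.942) for genes lower in both. For genes higher in both it was 1.41 (1.15 to 1.72), and expression in HepG2 was not adjusted for in either. Among them were the metalloproteinase gene MMP11 (0.46 and 1.75), TF (0.32 and 1.99), SERPINF1 (0.91 and 1.41) and the histone deacetylase gene HDAC5 (0.45 and 1.40), TF having an edgeR adjusted p of 0.0518 in shFKBP9 in the fit over all 9 libraries.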

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

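Voom with quality weights, the list results with library totals or RLE size factors, and the strata of expression and length were chosen after seeing the data. For shFKBP9, 5833 called genes became 1650 with all 9 libraries in 1 fit and 473 with a 2-fold threshold, and 4483 to 5567 when 1 library was left out. For the libraries labelled shIGF2BP1, 2048 became 3506 with all 9 libraries, 7540 with voom quality weights, 814 with a 2-fold threshold, and 918 to 4279 when 1 library was left out. Leaving out 1 library gave 2503 to 6472 genes in the direct comparison (4031), 394 to 1928 genes shared in direction (810) and correlations of 0.109 to 0.319 (0.223), which was 0.0938 to 0.202 with separate controls for each hairpin group (0.0938, 0.202, 0.124, 0.102, 0.168 and 0.109). The 12 lists of shFKBP9 became 0 with an estimated correlation, and 8 to 13 without 1 library. With fry, which tests a list against no change and not against other genes as camera does, 19 passed. The 4 lists of the libraries labelled shIGF2BP1 became 0 with an estimated correlation, 8 with a filter of 1 CPM, 7 with fry and 9 with library totals, and 4 to 10 without 1 library. Odds ratios of m6A genes moved to 1.01 (higher) and 0.974 (lower) in shFKBP9 within strata of expression and length, and to 0.926 (lower) with the combined peak list. Without 1 library they ranged over 1.33 to 1.52 (higher) and 0.769 to 0.917 (lower) in shFKBP9, and over 1.86 to 2.54 and 0.531 to 0.813 in the libraries labelled shIGF2BP1. Fewer libraries lower the power by construction. The fit over all 9 libraries uses 1 spread per gene for all groups. Their biological coefficients of variation were 27.8% in the libraries labelled shIGF2BP1, 9.46% in shControl and 6.45% in shFKBP9. That fit thus sets a wider spread for shFKBP9 and a narrower one for the libraries labelled shIGF2BP1. An estimated correlation leaves the list test few degrees of freedom. The cause of the other moves was not tested. No called list and no call of a named gene turned its direction, but the balance of calls did. In shFKBP9 the 2938 higher and 2895 lower genes became 677 and 973 with all 9 libraries and 2877 and 2902 with DESeq2. In the libraries labelled shIGF2BP1 the 1239 and 809 became 1206 and 1326 with library totals, 1163 and 1357 with limma on FPKM, and 3752 and 3788 with voom quality weights.

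With the replicate block, 5128 genes were called in shFKBP9 (5114 of the 5833), 1829 in the libraries labelled shIGF2BP1 (1713 of the 2048) and 3652 in the direct comparison, with 673 shared in direction, a correlation of 0.195, and 9 and 6 lists. The block's odds ratios of m6A genes were 1.37, 0.852, 1.89 and 0.689 (higher and lower in shFKBP9, then higher and lower in the libraries labelled shIGF2BP1). The shFKBP9 numbers did not pair with shControl (same-number correlations -0.36, -0.32 and 0.18), and replicates 1 and 2 correlated better with another number; with the block their mitochondrially encoded, WNT and fibroblast marker lists had adjusted p = 0.0564. For the libraries labelled shIGF2BP1 the block added the glycolysis and histone lists and changed no other call of a list or of a gene named in the report.

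Over 278 named gene results and 4144 alternative values, 3850 kept their side of the threshold, 162 passed it and 132 lost it. Over 53 list results and 635 values, 568 kept it, 35 passed it and 32 lost it. DESeq2 called 5679 of the 5833 and all 2048 of the 2048 genes. With 50% reciprocal overlap the replicates shared 4620 peaks. The stronger part of each peak list could not be taken, as scores are 0, and the motif alternatives were not run without a genome sequence. Depth limits what can be said of genes with few counts; no alternative varied it, and the simulated recovery of 41.8% at 2-fold in the libraries labelled shIGF2BP1 was not split by expression.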

Other observations

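The 6 gene lists of the first paragraphs were written after the leading genes had been seen, so their counts describe those genes and are no independent evidence. Acute phase and secreted defence proteins, of which some also belong to the liver-secreted list, were higher in 17 of 18 tested members in the libraries labelled shIGF2BP1, with a median log2 change of 2.69 (also with the 2 members absent from the controls set at their bound against 3 counts), and camera adjusted p = 5.01e-18 (adjusted p = 0.0203 with an estimated correlation). PI3, an elastase inhibitor gene, stood at 0.797 and 6.06 CPM in shControl and these libraries, CFB, the complement factor B gene, at 0.686 and 3.95 CPM, and HPX, the hemopexin gene, at 27.9 and 92.9 CPM. In shFKBP9, 9 of 14 members rose and none fell (camera adjusted p = 9.71e-05, adjusted p = 0.263 with an estimated correlation). SRF and actin cytoskeleton genes fell in 13 of 17 members in the libraries labelled shIGF2BP1 (median -1.04, camera adjusted p = 3.74e-10, adjusted p = 0.139 with an estimated correlation), among them FHL2 (-1.88), MYL9 (-1.75) and TPM1 (-1.37), while SRF itself stood at 69.6 and 69.5 CPM. In shFKBP9 the same list had 4 higher and 5 lower members (camera adjusted p = 0.637), with CNN1 and TAGLN rising.

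Mitochondrial ribosomal protein genes fell in 34 of 48 members in shFKBP9 and rose in none (camera adjusted p = 6.22e-08, adjusted p = 0.397 with an estimated correlation), MRPL18 by 0.55 on the log2 scale (-0.55) and MRPL16 by 0.53 (-0.53). Against genes of the same length and expression their median log2 difference was -0.11, in place of a raw -0.30. Translation initiation and elongation factors fell in 19 of 31 and rose in 3 (camera adjusted p = 6.03e-04, adjusted p = 0.397 with an estimated correlation), with a matched difference of -0.06 in place of -0.21. In the libraries labelled shIGF2BP1 these lists had 3 lower members each (camera adjusted p = 0.0553 and 0.0341, adjusted p = 0.579 and 0.139 with an estimated correlation), with the poly(A)-binding protein gene PABPC1 at -1.24. Cargo export from the endoplasmic reticulum had 2 of 26 members higher there (0.0710) and N-glycan synthesis 6 of 27 (0.0230, adjusted p = 0.139 with an estimated correlation); in shFKBP9 both had camera adjusted p = 0.637.

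In what follows, the tests of copy number, of gene length and of scaling were chosen before their results were seen, and the others only afterwards. For each of the 3 comparisons of 3 against 3 libraries, the 10 possible splits are too few for a share under 0.05. The real split called 5833, 2048 and 2933 genes (the last within the 6 libraries of shFKBP9 and shIGF2BP1 labels), the highest other split called 0, and 1 of the 10 splits gave as many genes in each case.

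The libraries labelled shIGF2BP1 changed strongly although IGF2BP1 mRNA in replicate 1 was near the control level (90.6% of the control mean, against 58.8% and 72.8% in replicates 2 and 3). If the response followed the mRNA, replicate 1 should respond least. Along the called genes its response was 1.09 times that of replicate 2, a measure that favours genes alike in all 3 libraries. A second measure, whose limits were set after both values had been seen, used only genes called without replicate 1 and gave 0.878. Those genes were chosen and weighted by their changes in replicates 2 and 3, which favours these 2 libraries. The fall of IGF2BP1 mRNA in replicate 1 was 0.228 of that in replicate 2. Whether the response follows the mRNA cannot be told apart from other causes with these 3 libraries, since no protein was measured and the order of the libraries differed between the measures. Copy-number differences between the cells may also contribute and stay open. The spread of 10 Mb window medians was 1.38 times its mean over random gene positions. That was above the highest random value of 1.12 and below the 1.5 set beforehand. In shFKBP9 the same measure gave 1.71 (highest random value 1.16), past 1.5, so copy number stays open there too. Random positions did not keep gene length, which went with the log2 change in shFKBP9 (Spearman 0.357 across genes). The measure is therefore not specific to copy number.

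Replicate 3 of the libraries labelled shIGF2BP1 lay between replicates 1 and 2 for 99.8% of 2133 genes that separate them, at a median fraction of 0.440 of replicate 1 (quartiles 0.387 and 0.489). Its residual from a linear blend of the other pair was 3.13 times the sampling variance at 1000 to 5000 counts (95% bootstrap interval 2.84 to 3.28). That was below every shControl or shFKBP9 library fitted the same way (4.33 to 31.7, the lowest with an interval of 4.05 to 4.59). These intervals resample genes within a library and do not measure how the ratio varies between libraries. The low value therefore does not exclude an independent culture with the usual replicate noise. The residual over sampling variance rose 1.23-fold from low counts (2.55) to 1000 to 5000 counts (3.13). A small rise is what a blend of RNA or reads of replicates 1 and 2 predicts. Cultures holding 2 cell states in different shares predict it as well. Above 5000 counts the ratio was higher, at 4.37, so the small rise did not hold over all counts. The shControl and shFKBP9 libraries stood at 9.61 to 107 there. The same values bear on both explanations, so these were not separated, and neither changes the group of any library. If replicate 3 may be such a blend, fewer than 3 independent samples stand behind the calls, and 918 genes were called without it.

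Ribosomal protein genes were lower in shFKBP9 at a mean log2 CPM of 8.29, 8.46 and 8.37 against 8.92, 8.65 and 8.76 in shControl. Scaling argues against itself as the cause, since the mean change was -0.36 with library totals and -0.41 with RLE size factors. A bias by gene length and expression level may explain part of it: against genes of the same length and expression the median difference was -0.18 in place of -0.41, a ratio of 0.451. Most of the remaining difference had the same sign (quartiles -0.29 and -0.07). The labels give no measure of RNA quality, and an effect of FKBP9 depletion itself stays open and was not tested apart from length.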
